A study of Mus musculus with 12 samples.

How the data were processed

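Bulk RNA-seq of 12 mouse tumors was re-analysed, 3 in each of 4 groups: empty vector (EV) or p53ERTAM, each under vehicle or combo (ORIN1001 and docetaxel). RNA was extracted with a Direct-zol kit and stranded libraries of ribosome-depleted total RNA were made with an Illumina kit, per the labels' protocols. FastQC, fastp, STAR, featureCounts and the build GRCm38.p5 are named per the submitters' processing notes, without versions. The annotation release and the strand setting of the counting are not stated, and the labels do not say which mice received tamoxifen. The deposited files hold raw counts per gene, per the file headers in the featureCounts layout, with no normalization. Each of the 12 files lists 52636 genes with the summed exon length. Of these identifiers 52403 were matched to a symbol by a GENCODE annotation and 233 were not. Low counts (1 to 20) were even in 66.3 to 71.7% of cases against 49.2 to 52.1% of counts above 200, as when both mates of a pair are counted. Totals per library were 13484873 to 24424964 counts. A gene without counts in a group of 3 libraries is limited to 3 counts over the group, 0.0409 to 0.0636 CPM, which covers counting error only. Folds against such a group are given as lower bounds at that floor. If both mates of a pair were counted, 3 fragments would give more than 3 counts. The floor would then be too low and the bounds too high.

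Groups were taken from the sample titles before the data were examined, and the comparisons, gene lists, named-gene rule and the first set of alternatives were fixed at the same time. Of 31622 genes with at least 1 count, 17970 passed edgeR's filterByExpr over the 4 groups, which kept at least 99.8% of the counts in every library. TMM factors were 0.941 to 1.05 and the biological coefficient of variation was 0.221. Expression was tested by the edgeR quasi-likelihood F-test (robust) in 1 fit of 4 group means with 8 residual degrees of freedom, for 7 contrasts: combo against vehicle in each vector, p53ERTAM against EV under each treatment, their interaction, and both main effects. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. On simulated data, where 50 genes per fold were changed, the test recovered 46% of 2-fold, 70% of 4-fold and 94% of 8-fold changes for combo in EV tumors, 42%, 78% and 94% in p53ERTAM tumors, and 20%, 60% and 78% for the interaction, with 3.39%, 3.33% and 9.09% false calls. The simulation changed 200 genes in all, while the data gave 7169, 1129 and 6473 calls for these comparisons. Its rates may therefore not hold for the data.

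There were 29 gene lists: p53 target genes, dsRNA sensing, interferon-stimulated genes, pyroptosis and necroptosis, XBP1 targets, RIDD substrates, PERK and ATF4 targets, ATF6 targets, mitosis, DNA replication, tubulins, senescence secretome, MHC class I and class II presentation, and markers of T cells, NK and cytotoxic cells, B and plasma cells, macrophages, neutrophils, dendritic cells, fibroblasts, endothelium, adipocytes, skeletal muscle, epithelium, basal and mesenchymal cells, milk proteins, keratinocytes and erythroid cells. Some genes stand in 2 lists, among them Tapbp (RIDD substrates and MHC class I), Pdgfrb (RIDD substrates and fibroblasts) and Hyou1 (XBP1 and ATF6 targets). The RIDD substrates Sparc and Pdgfrb are also abundant in stroma. The senescence secretome list also holds the cell-cycle inhibitor genes Cdkn2a and Cdkn2b, which are not secreted factors. Lists were tested by camera on voom values with a preset inter-gene correlation of 0.01, adjusted over the 29 lists of a comparison. Camera sets a list against all other genes tested, noncoding ones included, and the 29 lists were not tested among protein-coding genes alone. Camera with an estimated correlation and fry were the alternatives. No camera call held with an estimated correlation. By fry, which asks whether a list's genes move on balance in 1 direction, the adjusted p was below 0.05 for 6 of 8 called lists for combo in EV tumors, 11 of 17 in p53ERTAM tumors, 6 of 8 for the vectors under vehicle, 16 of 17 under combo and 12 of 15 for the interaction.

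The genes named are Trp53, Esr1, Cdkn1a, Mdm2, Xbp1, Ern1, Dnajb9, Zbp1 and Gsdmd; per comparison up to 8 genes in each direction with the largest fold change among those with adjusted p below 0.05, a mean of at least 1 CPM in the higher group and no overlap between the groups (not required for the interaction), leaving out unnamed, immunoglobulin, T cell receptor, pseudogene and mitochondrial genes; and 2 to 4 members of smallest p of each list described. Counts of paralogs with shared sequence, such as tubulins, hemoglobins, MHC genes and interferon-induced families, can include reads of one another. Genes higher with combo in EV tumors were read in the p53ERTAM tumors by their median log2 fold change, by camera, and by a score per library, the mean of log2(TPM + 1), compared by an exact two-sided permutation test. TPM were computed from the counts and exon lengths.

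The first set of alternatives was the DESeq2 Wald test, DESeq2 size factors, no filter, the replicate number as a block, leaving out the 7 genes with over 1% of a library, voom with sample quality weights, a test against a fold of 1.5, only the 2 groups compared, leaving out each library in turn, a list of the 200 genes of smallest p or of genes over 2-fold by mean TPM for the selection, and a TPM pseudocount of 0.1. Chosen after seeing the data were offsets for GC content and length (loess, span 0.3), halved counts, the EV combo libraries left out of the fit, protein-coding genes only, and camera with an estimated correlation for the genes raised by combo in EV tumors. Overlaps are given for comparisons that share no library. The study's list of dsRNA-containing genes with p53 binding was not used here. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.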

Results

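RNA was sequenced from 12 bulk tumors of 2153L, a genetically engineered mouse mammary tumor that the labels class as triple-negative breast cancer, grown in the mammary fat pad of female BALB/c mice. The tumors carried an empty vector (EV) or p53ERTAM, the tumor suppressor p53 fused to a tamoxifen-responsive hormone-binding domain of the estrogen receptor. Mice received vehicle or the combination (combo) of ORIN1001, an inhibitor of the RNase of the endoplasmic reticulum stress sensor IRE1α (150 mg/kg daily), and docetaxel, a microtubule-stabilising drug (20 mg/kg weekly), for 8 days. Each of the 4 groups had 3 tumors. The labels do not say which mice received tamoxifen. Total counts per library were 20431888 to 23188928 in EV vehicle, 14433361 to 17601245 in EV combo, 13484873 to 19461986 in p53ERTAM vehicle and 21914913 to 24424964 in p53ERTAM combo. Between 21847 and 23910 genes had at least 1 count in a library, and 17970 genes were tested.

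Cdkn1a, Mdm2 and Esr1 were higher in p53ERTAM than in EV tumors. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, stood at 32.8 ± 10.8 CPM, library-size-scaled counts (SD, n = 3) in EV vehicle and 33.8 ± 17.5 in EV combo, against 122 ± 33.1 in p53ERTAM vehicle and 181 ± 16.9 in p53ERTAM combo. Averaged over both treatments it was higher by 2.16 on the log2 scale (SE 0.233, edgeR adjusted p = 2.19e-05). Esr1, the estrogen receptor gene, was higher by 1.80 (SE 0.168, edgeR adjusted p = 3.83e-06), from 9.10 ± 3.58 to 30.6 ± 2.20 CPM under vehicle and from 10.4 ± 1.85 to 37.5 ± 1.21 under combo. Counts of Esr1 and Trp53 may include reads of the p53ERTAM fusion, which was not tested. Mdm2, the ubiquitin ligase that p53 induces and that degrades p53, was higher by 0.47 (SE 0.0934, edgeR adjusted p = 0.00125). Of 30 p53 targets, 19 were higher and 4 lower over both treatments (20 and 4 adjusted over the list alone; median 0.53, camera adjusted p = 7.57e-05, and adjusted p = 0.155 with an estimated correlation). The list was not called under vehicle alone (camera adjusted p = 0.0548). Trp53 itself (ENSMUSG00000059552.13, GRCm38 chromosome 11, 69580359 to 69591873) differed little: 45.7 ± 8.08 and 46.5 ± 5.99 CPM in EV vehicle and combo, 51.5 ± 4.53 and 61.1 ± 3.72 in p53ERTAM vehicle and combo. Its mean difference was 0.28 (SE 0.0983, edgeR adjusted p = 0.0336). That call was lost without EV vehicle replicate 1 (adjusted p = 0.0710) or 3 (0.0632), EV combo replicate 3 (0.0829), p53ERTAM vehicle replicate 3 (0.0755) or p53ERTAM combo replicates 2 (0.0564) and 3 (0.0766), and with GC and length offsets (0.112).

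**Figure D1:**
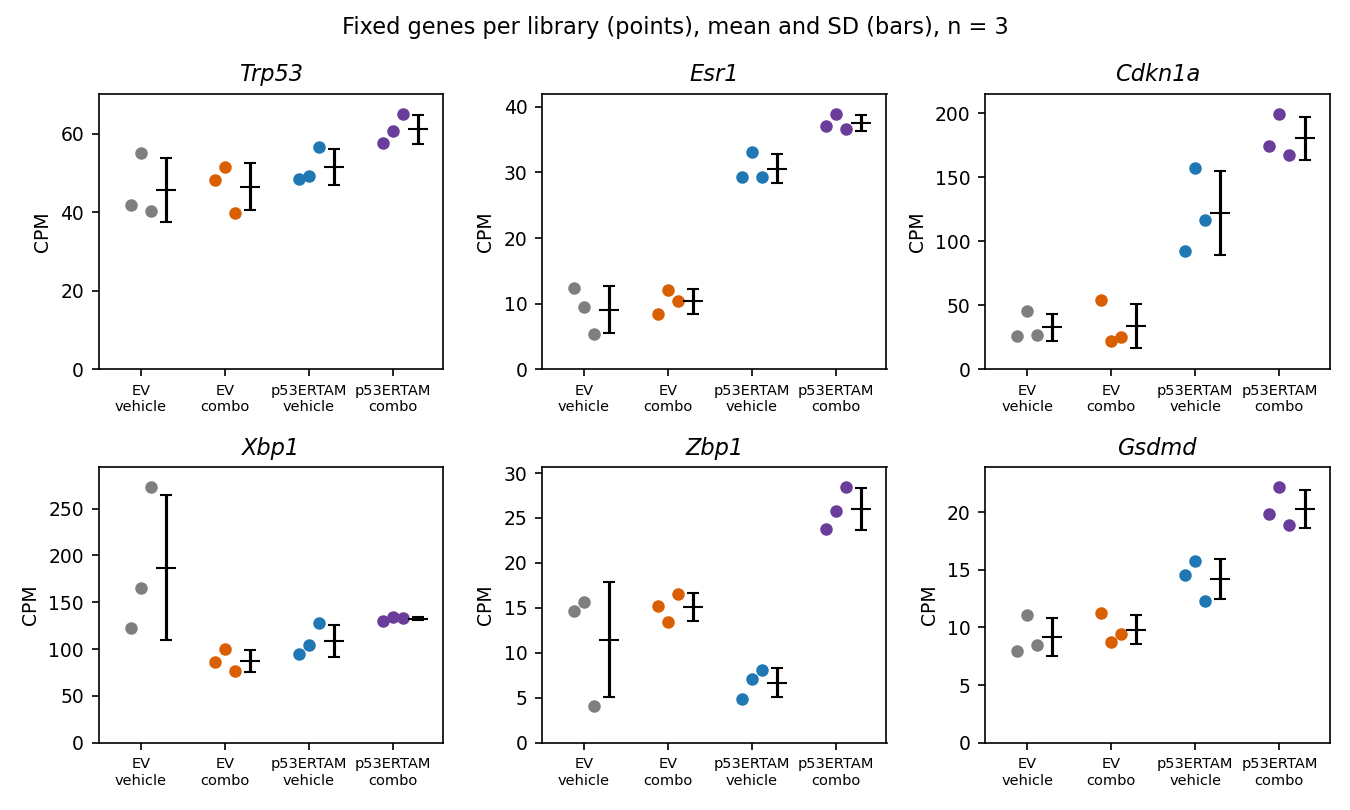
CPM of the genes fixed before the data were examined, by group; each point is 1 tumor, and the bar and whiskers are the mean and SD of 3 tumors. Cdkn1a and Esr1 were higher in p53ERTAM than in EV tumors under both treatments, while Trp53 lay between 39.8 and 65.0 CPM in the 12 libraries.

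The 3 EV combo libraries differed from the other 9 in the kinds of RNA they held. Gm26917, annotated as a long noncoding RNA, took 10.7 to 11.1% of their counts and 0.133 to 1.10% in the other 9. Whether the reads counted there come from that RNA was not tested. Xist, the noncoding RNA of the inactive X chromosome, took 1.0 to 1.15% against 0.0776 to 0.487%. Protein-coding genes held 80.9 to 81.7% of their counts against 86.7 to 95.8%, and the mitochondrial genome 0.703 to 0.957% against 1.43 to 2.16%. TEC genes, an annotation class of transcribed regions still awaiting experimental support, held 0.779 to 0.842% in EV combo, 0.185 to 0.333% in EV vehicle, 0.427 to 0.890% in p53ERTAM vehicle and 0.267 to 0.402% in p53ERTAM combo. Among the other 9 libraries, p53ERTAM vehicle replicate 2 came closest: 86.7% protein-coding, 0.890% TEC, 1.51% Gm42418 (1.48 to 1.67% in EV combo) and 2.43% Malat1 (1.11 to 1.59% in EV combo), at the lowest total of 13484873 counts. Gm26917, Gm42418, Malat1 and Xist were singled out after their values were seen. Comparisons that include EV combo carry this difference in make-up.

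**Figure D2:**
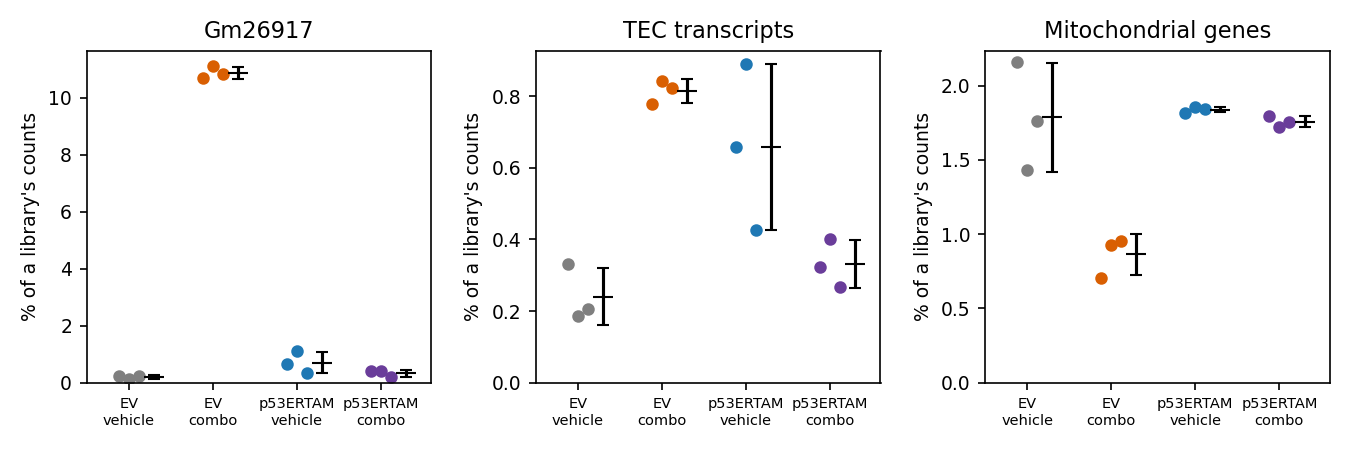
Percent of each library's counts in RNA classes and single genes, by group; each point is 1 tumor, and the bar and whiskers are the mean and SD of 3 tumors. Gm26917 took 10.7 to 11.1% of the counts in the EV combo libraries and at most 1.10% in the other 9.

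The first comparison asked what combo did in EV tumors, the step from which the series' design takes its combo-induced genes. Genes of protein folding and secretion fell and stromal genes rose. Xbp1, whose mRNA IRE1α splices into the active transcription factor, fell by 1.10 on the log2 scale (SE 0.229, edgeR adjusted p = 0.00278), from 187 ± 77.2 to 87.4 ± 11.5 CPM (SD, n = 3). Of 20 XBP1 targets, 13 fell (14 adjusted over the list alone) and 0 rose, with a median log2 fold change of -0.55 (camera adjusted p = 0.000247, and adjusted p = 0.843 with an estimated correlation). They included the secretory-pathway genes Serp1 (-1.33), Ssr3 (-0.79) and Sec61a1 (-0.56). Of 10 ATF6 targets, 8 fell (8 adjusted over the list alone; median -0.44, camera adjusted p = 0.00416, and adjusted p = 0.843 with an estimated correlation), among them the chaperones Canx (-0.73) and Calr (-0.56). Of 16 PERK and ATF4 targets, 5 fell (5 adjusted over the list alone; median -0.35, camera adjusted p = 0.0344, and adjusted p = 0.843 with an estimated correlation), including the stress transcription factor Atf4 (-0.59) and Psat1 (-1.18), an enzyme of serine synthesis. Ern1, which encodes IRE1α, had a log2 fold change of 0.020 (edgeR adjusted p = 0.893), and the XBP1 target Dnajb9 -0.54 (edgeR adjusted p = 0.102). Of 10 RIDD substrates, mRNAs that IRE1α is known to cleave directly, 3 rose and 2 fell (3 and 3 adjusted over the list alone; median -0.099, camera adjusted p = 0.880).

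Cell-division and epithelial genes also fell in EV tumors given combo. Of 24 DNA replication genes, 14 fell (15 adjusted over the list alone; median -0.45, camera adjusted p = 0.000247, and adjusted p = 0.967 with an estimated correlation), including Fen1 (-1.11), Gins2 (-0.96) and Ccne1 (-1.33), the cyclin of S-phase entry. Of 24 mitosis genes, 7 fell (7 adjusted over the list alone; median -0.32, camera adjusted p = 0.0185, and adjusted p = 0.980 with an estimated correlation), with the spindle motor Kif11 at -0.81. Of all 17970 genes tested, 3783 were called lower. The genes that camera sets a list against include 1146 TEC genes with a median of 1.84 in this comparison. The 13911 protein-coding genes had a median of -0.13. Of 10 epithelial markers, 6 fell (8 adjusted over the list alone; median -0.57, camera adjusted p = 0.00475, and adjusted p = 0.843 with an estimated correlation), among them the adhesion genes Cdh1 (-0.96) and Epcam (-0.87). Of 10 fibroblast markers, 7 rose (7 adjusted over the list alone; median 1.17, camera adjusted p = 0.00203, and adjusted p = 0.843 with an estimated correlation), including Pdgfrb (1.48) and the collagen gene Col3a1 (1.79). Of 10 endothelial markers, 5 rose (7 adjusted over the list alone; median 0.81, camera adjusted p = 0.0213, and adjusted p = 0.967 with an estimated correlation). Interferon-stimulated genes did not move as a group: 2 of 28 rose, among them Herc6 (1.23), and 2 fell (1 and 1 adjusted over the list alone), with a median of -0.031 (camera adjusted p = 0.677). Of 16 dsRNA-sensing genes, 2 rose, among them Oas1b (1.16), and 2 fell, among them Ticam1 (-0.67), the adaptor of the dsRNA receptor TLR3 (2 and 1 adjusted over the list alone; median 0.093, camera adjusted p = 0.761).

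In all, edgeR called 7169 genes between combo and vehicle in EV tumors, 3386 higher and 3783 lower. Which direction led depended on scaling and size: 3661 were higher and 3304 lower with DESeq2 size factors, and 1428 higher and 442 lower against a fold of 1.5. The largest rises among the named genes included those of the gap junction gene Gjc3 and of Dpp10, which encodes a potassium channel partner (6.03, SE 1.11). Gjc3 was absent from the EV vehicle libraries and, at the floor of 3 counts, at least 24.8-fold higher with combo. The large falls included those of the G protein subunit gene Gnao1 (-5.11, SE 0.955) and the claudin gene Cldn10 (-4.94, SE 0.911). Among the lists, the PERK and ATF4 call was lost without EV vehicle replicate 2 (0.0825) or 3 (0.0554) or EV combo replicate 2 (0.0787) or 3 (0.0923), mitosis without EV vehicle replicate 3 (0.141) or EV combo replicate 2 (0.0790), and endothelial markers without EV vehicle replicate 3 (0.0611) or EV combo replicate 3 (0.152). The PERK and ATF4 median was -0.58 to -0.20 over all refits without 1 library. Medians were -0.18 for mitosis without EV vehicle replicate 3 and 0.52 for endothelial markers without EV combo replicate 3. With GC and length offsets, PERK and ATF4 targets (0.223), mitosis (0.0717) and epithelial markers (0.0717) lost their calls, as did Atf4 (0.0522), while Dnajb9 became a call (-0.98, adjusted p = 0.0164). The interferon list became a call without EV vehicle replicate 2 (median 0.42, adjusted p = 0.0186).

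The next comparison asked what combo did in p53ERTAM tumors. Interferon-stimulated genes rose nearly as a whole: 26 of 28 were higher (28 adjusted over the list alone), with a median log2 fold change of 1.5 (camera adjusted p = 5.07e-26, and adjusted p = 0.145 with an estimated correlation). Ifit1, an antiviral RNA-binding protein gene, rose by 2.30 (SE 0.246, edgeR adjusted p = 0.00114). The signalling gene Stat2 (1.26) and the feedback regulator Usp18 (2.26) rose with it. Of 16 dsRNA-sensing genes, 10 rose (12 adjusted over the list alone; median 1.02, camera adjusted p = 2.17e-09, and adjusted p = 0.145 with an estimated correlation), among them the RNA sensor Ddx58 (0.90) and the dsRNA-activated kinase Eif2ak2 (1.07). Zbp1, a sensor of Z-form nucleic acid that can trigger necroptosis, rose by 1.96 (SE 0.377, edgeR adjusted p = 0.0169), from 6.69 ± 1.61 to 26.0 ± 2.30 CPM (SD, n = 3). That call was lost without p53ERTAM vehicle replicate 1 (adjusted p = 0.0734) or 2 (0.0692) or p53ERTAM combo replicate 1 (0.0624) or 3 (0.0725).

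Antigen-presentation and macrophage genes rose in the same tumors. Of 11 MHC class I genes, 9 rose (11 adjusted over the list alone; median 0.96, camera adjusted p = 2.17e-09, and adjusted p = 0.145 with an estimated correlation). Of 7 MHC class II genes, 2 rose (7 adjusted over the list alone; median 1.79, camera adjusted p = 2.47e-06, and adjusted p = 0.230 with an estimated correlation). Of 12 macrophage markers, 8 rose (10 adjusted over the list alone; median 1.32, camera adjusted p = 2.17e-09, and adjusted p = 0.145 with an estimated correlation), including the complement genes C1qa (1.61) and C1qc (1.53) and the growth factor receptor Csf1r (1.35). Of 7 NK and cytotoxic cell markers, 1 rose, the chemokine gene Ccl5 (2.10, SE 0.320; 4 adjusted over the list alone; camera adjusted p = 0.000556, and adjusted p = 0.230 with an estimated correlation). T cell markers had a median of 1.18 with 0 of 11 members called (0 adjusted over the list alone; camera adjusted p = 0.00324, and adjusted p = 0.518 with an estimated correlation). Of 16 pyroptosis and necroptosis genes, 3 rose (7 adjusted over the list alone; median 0.57, camera adjusted p = 2.29e-06, and adjusted p = 0.145 with an estimated correlation), namely the inflammasome genes Casp1 (1.04), Pycard (1.37) and Casp4 (1.0). Each of these 3 lost its call without p53ERTAM vehicle replicate 1 or 2 or p53ERTAM combo replicate 1 or 3, where adjusted p was 0.0696 to 0.107 for Casp1, 0.0818 to 0.109 for Pycard and 0.0841 to 0.138 for Casp4. Casp4 also lost it without p53ERTAM combo replicate 2 (0.0560) or with the EV combo libraries left out of the fit (0.0524). Gsdmd, the pore-forming protein of pyroptosis, had a log2 fold change of 0.51 (edgeR adjusted p = 0.0953), and was called by DESeq2 (adjusted p = 0.0366) and by voom with quality weights (0.0203).

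Of 30 p53 target genes, 3 rose with combo in p53ERTAM tumors and 1 fell (7 and 1 adjusted over the list alone; median 0.27, camera adjusted p = 4.84e-05, and adjusted p = 0.145 with an estimated correlation). Ccng1, the p53-induced cyclin G1 gene, rose by 0.90 (SE 0.118, edgeR adjusted p = 0.00359) and Ephx1 by 1.33 (SE 0.185, edgeR adjusted p = 0.00417). Cdkn1a had a log2 fold change of 0.57 (edgeR adjusted p = 0.294; 0.0387 by voom with quality weights). Of 9 tubulin genes, whose protein docetaxel binds, 4 rose (7 adjusted over the list alone; median 0.58, camera adjusted p = 1.32e-05, and adjusted p = 0.150 with an estimated correlation), with Tubb2a at 1.12 (SE 0.147). Of 15 senescence secretome genes, 3 rose (5 adjusted over the list alone; median 0.58, camera adjusted p = 0.00454, and adjusted p = 0.451 with an estimated correlation). Krt14, a basal keratin gene, fell by 2.13 on the log2 scale (SE 0.283), as did the receptor gene Fgfr2 (-2.89, SE 0.210) and the hemidesmosome collagen Col17a1 (-2.62, SE 0.391). The basal and mesenchymal list was not called: 3 of 11 were lower (1 higher and 4 lower adjusted over the list alone), with a median of 0.033, a mean of -0.43 and camera pointing downward (adjusted p = 0.387). All 3 erythroid markers fell (3 adjusted over the list alone; median -4.86, camera adjusted p = 0.000348, and adjusted p = 0.145 with an estimated correlation). Their calls were lost when single libraries were left out, Hbb-bs without p53ERTAM combo replicate 3 (adjusted p = 0.0592), Alas2 without p53ERTAM vehicle replicate 2 (0.0603) or combo replicate 1 (0.0629) or 3 (0.0886), and Hbb-bt without vehicle replicate 1 (0.0697) or 2 (0.0631) or combo replicate 1 (0.112), 2 (0.0696) or 3 (0.0779).

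The 20 XBP1 targets showed no call in p53ERTAM tumors (0 adjusted over the list alone; median 0.12, camera adjusted p = 0.233), and Xbp1 had a log2 fold change of 0.29 (edgeR adjusted p = 0.469). Stress-response sets moved upward: ATF6 targets (median 0.23, 0 of 10 called, 3 adjusted over the list alone, camera adjusted p = 0.0124, and adjusted p = 0.482 with an estimated correlation) and PERK and ATF4 targets (median 0.29, 1 of 16 higher, 5 adjusted over the list alone, camera adjusted p = 0.0339, and adjusted p = 0.451 with an estimated correlation). So did RIDD substrates (median 0.42, 1 of 10 higher, 1 adjusted over the list alone, camera adjusted p = 0.00510, and adjusted p = 0.230 with an estimated correlation). Mitosis (median -0.21, 1 of 24 lower, 1 adjusted over the list alone, camera adjusted p = 0.00324, and adjusted p = 0.553 with an estimated correlation) moved downward. DNA replication did as well (median -0.18, 2 of 24 lower, 3 adjusted over the list alone, camera adjusted p = 0.0346, and adjusted p = 0.604 with an estimated correlation). Without p53ERTAM vehicle replicate 1 the calls of RIDD substrates (0.0532), PERK and ATF4 targets (0.122), mitosis (0.231), senescence secretome (0.0551) and DNA replication (0.842) were lost. The DNA replication median then changed sign to 0.026, the mitosis median shrank to -0.060 without changing sign, and the RIDD median was 0.24. Without vehicle replicate 2 the medians were 0.13 for PERK and ATF4 targets, 0.14 for ATF6 targets and -0.28 for DNA replication. Without vehicle replicate 3 they were 0.36 for ATF6 targets and 0.89 for the senescence secretome. ATF6 targets lost theirs without p53ERTAM vehicle replicate 2 (0.0710), and DNA replication without vehicle replicate 3 (0.0861) or combo replicate 2 (0.0670), and PERK and ATF4 targets with GC and length offsets (0.127).

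In all, edgeR called 1129 genes between combo and vehicle in p53ERTAM tumors, 593 higher and 536 lower, and the count rested on single libraries. It was 121, 183 and 2130 without p53ERTAM vehicle replicates 1, 2 and 3, and 77, 514 and 96 without p53ERTAM combo replicates 1, 2 and 3. The balance of directions moved too: 63 higher and 14 lower without combo replicate 1, and 79 and 17 without combo replicate 3. Lower genes led without vehicle replicate 3 (984 higher and 1146 lower), by DESeq2 (1113 and 1189) and by voom with quality weights (1861 and 1887). Of the 28 interferon-stimulated genes, 9, 10 and 25 rose without vehicle replicates 1, 2 and 3, and 6, 16 and 12 without combo replicates 1, 2 and 3, and the camera call of the list held each time. Counts of MHC class I genes were 0, 0, 8, 1, 4 and 0 in the same order, and of macrophage markers 3, 3, 7, 3, 7 and 3. Of the 53 named genes called here, 37 lost their call in at least 1 of the refits without 1 library. Those that kept theirs included Fgfr2, Col17a1, Krt14, Ccng1, Ephx1, Ddx58, Eif2ak2, Ifit1, Stat2, Usp18, Tubb2a, Ccl5, C1qa, C1qc and Csf1r.

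**Figure D3:**
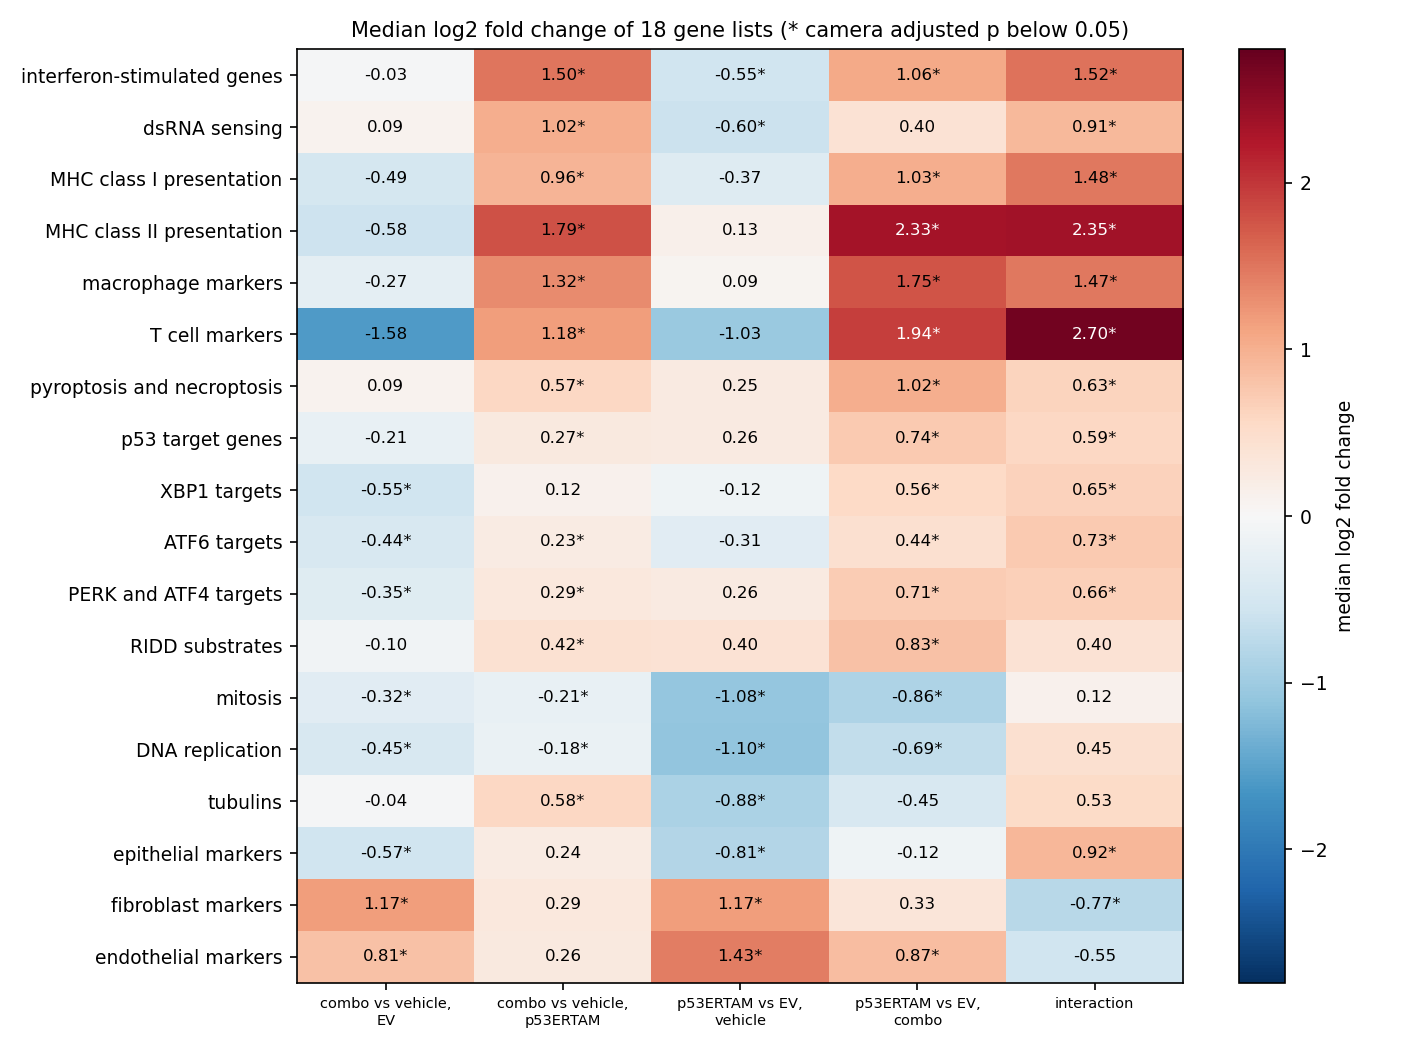
Median log2 fold change of 18 gene lists (vertical axis) in 5 comparisons (horizontal axis); colour and number give the median, and an asterisk marks a camera adjusted p below 0.05. Interferon-stimulated genes had medians of -0.031 in EV tumors and 1.5 in p53ERTAM tumors, and the XBP1 targets -0.55 and 0.12.

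Whether combo acted differently in the 2 kinds of tumor was tested as the interaction of vector and treatment, in which a positive value means a larger rise or a smaller fall in p53ERTAM tumors. The interferon response, antigen presentation and the folding genes differed. Over all 17970 genes tested the median difference was 0.13, and it was 0.0445 in a fit of protein-coding genes alone. The genes that camera sets a list against include the 1146 TEC genes, with a median of 1.84 for combo in EV tumors. Of 28 interferon-stimulated genes, 23 had a higher effect (24 adjusted over the list alone), with a median difference of 1.52 (camera adjusted p = 8.04e-07, and adjusted p = 0.5 with an estimated correlation). Ifit1 differed by 2.54 (SE 0.337, edgeR adjusted p = 0.000405). Differences in the same direction were found for dsRNA-sensing genes (9 of 16 higher, 9 adjusted over the list alone, median 0.91, camera adjusted p = 0.00581, and adjusted p = 0.5 with an estimated correlation). They were found for MHC class I genes (9 of 11 higher, 10 adjusted over the list alone, median 1.48, camera adjusted p = 0.000686, and adjusted p = 0.490 with an estimated correlation), MHC class II genes (7 of 7 higher, 7 adjusted over the list alone, median 2.35, camera adjusted p = 0.00828, and adjusted p = 0.540 with an estimated correlation) and macrophage markers (9 of 12 higher, 10 adjusted over the list alone, median 1.47, camera adjusted p = 0.00103, and adjusted p = 0.490 with an estimated correlation). EV vehicle replicate 2 stood apart on immune lists, with mean log2 CPM of 6.27 for MHC class II genes against 4.65 and 3.89 in the other EV vehicle libraries, 7.38 against 6.59 and 6.52 for MHC class I genes, and 2.28 against 0.26 and -0.80 for T cell markers. In EV tumors alone these lists had medians of -0.58, -0.49 and -1.58 with combo, and none was called (camera adjusted p = 0.738, 0.312 and 0.312). Without that library the MHC class II interaction median was 1.35 (camera adjusted p = 0.00486) and the T cell one 1.45 (camera adjusted p = 0.0606). B and plasma cell markers stood at 4.86 in EV vehicle replicate 2 against -0.007 and -1.04 in the other EV vehicle libraries. Zbp1 differed by 1.57 (SE 0.519, edgeR adjusted p = 0.0324), a call lost when any of 9 libraries was left out: EV vehicle 1 (0.0707) or 2 (0.0813), EV combo 1 (0.0605) or 2 (0.0668), p53ERTAM vehicle 1 (0.0812) or 2 (0.0636), or p53ERTAM combo 1 (0.0528), 2 (0.0571) or 3 (0.0702). It was also lost without a filter (0.1), with the replicate block (0.0590), with GC and length offsets (0.0588) and among protein-coding genes alone (0.0598).

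The fall of the folding genes in EV tumors had no counterpart in p53ERTAM tumors. Xbp1 differed by 1.38 (SE 0.321, edgeR adjusted p = 0.00609). Of 20 XBP1 targets, 11 had a higher effect (12 adjusted over the list alone; median 0.65, camera adjusted p = 0.000686, and adjusted p = 0.490 with an estimated correlation), including Serp1 (1.62) and Dnajb11 (1.02). Of 10 ATF6 targets, 7 did (7 adjusted over the list alone; median 0.73, camera adjusted p = 0.00113, and adjusted p = 0.490 with an estimated correlation). Of 16 PERK and ATF4 targets, 7 did (7 adjusted over the list alone; median 0.66, camera adjusted p = 0.00828, and adjusted p = 0.490 with an estimated correlation). Of 30 p53 targets, 11 had a higher and 3 a lower effect (14 and 3 adjusted over the list alone; median 0.59, camera adjusted p = 0.0204, and adjusted p = 0.490 with an estimated correlation), with Ccng1 at 1.80 (SE 0.168, edgeR adjusted p = 0.000146). Epithelial markers differed upward (6 of 10, 7 adjusted over the list alone, median 0.92, camera adjusted p = 0.00581, and adjusted p = 0.490 with an estimated correlation). Fibroblast markers differed downward (5 of 10, 5 adjusted over the list alone, median -0.77, camera adjusted p = 0.0260, and adjusted p = 0.5 with an estimated correlation). The fibroblast call was lost without EV combo replicate 3 (0.0753) or p53ERTAM combo replicate 2 (0.0645). With GC and length offsets, the calls of p53 targets (0.0579), pyroptosis and necroptosis genes (0.0579), PERK and ATF4 targets (0.0636), fibroblast markers (0.0520) and epithelial markers (0.0520) were lost. The edgeR test called 6473 genes, 3377 with a higher and 3096 with a lower effect in p53ERTAM tumors. With DESeq2 size factors 2943 were higher and 3252 lower, and against a fold of 1.5 801 were higher and 1792 lower.

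The combo responses of EV and p53ERTAM tumors, which share no library, overlapped beyond independence only among genes higher in EV and lower in p53ERTAM tumors. Of the 3386 genes higher with combo in EV tumors, 299 were lower with combo in p53ERTAM tumors, where independence gives 101, and 31 were higher in both, where it gives 112. Of the 299, 128 were TEC and 22 sense intronic genes, and the number went from 0 to 715 when single p53ERTAM libraries were left out. Another 64 genes were lower in both (113 by independence), and 121 were lower in EV and higher in p53ERTAM tumors (125 by independence). Across the 17970 genes, which are not independent replicates, the 2 log2 fold changes correlated with Pearson's r = -0.33 and Spearman's rho = -0.28.

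The vector comparison under vehicle asked what p53ERTAM did without drug. Genes of cell division were lower throughout: 24 of 24 mitosis genes (24 adjusted over the list alone; median -1.08, camera adjusted p = 8.22e-14, and adjusted p = 0.392 with an estimated correlation) and 24 of 24 DNA replication genes (24 adjusted over the list alone; median -1.10, camera adjusted p = 2.84e-14, and adjusted p = 0.392 with an estimated correlation). Mki67, the marker of cycling cells, was lower by 1.24 on the log2 scale (log2 fold change -1.24, SE 0.149, edgeR adjusted p = 9.52e-05), and the helicase gene Mcm6 had a log2 fold change of -1.47 (SE 0.164). Cdkn1a was higher by 1.9 (SE 0.327, edgeR adjusted p = 0.00107). Of 30 p53 targets, 10 were higher and 3 lower (11 and 3 adjusted over the list alone; median 0.26, camera adjusted p = 0.0548), with Ak1 at 1.27 and Pvt1 at 1.48 among the higher and Perp (-0.97) and Rps27l (-1.34) among the lower. The p53 target list became a call without EV vehicle replicate 2 (0.0177) or p53ERTAM vehicle replicate 2 (0.0206), and with GC and length offsets (0.0366).

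Cell-type markers differed between the vectors as well. Of 10 epithelial markers, 8 were lower in p53ERTAM tumors (8 adjusted over the list alone; median -0.81, camera adjusted p = 0.000267, and adjusted p = 0.392 with an estimated correlation), with the keratin Krt7 at -1.13. Of 10 fibroblast markers, 7 were higher (8 adjusted over the list alone; median 1.17, camera adjusted p = 0.000577, and adjusted p = 0.392 with an estimated correlation), including Col1a1 (2.38). Of 10 endothelial markers, 8 were higher (9 adjusted over the list alone; median 1.43, camera adjusted p = 0.000376, and adjusted p = 0.595 with an estimated correlation), including the tight junction gene Cldn5 (2.96). The 11 basal and mesenchymal markers parted: 6 were higher, such as the mesenchymal regulators Zeb1 (2.53) and Twist1 (2.19), and 5 lower, such as the basal genes Trp63 (-1.67) and Krt14 (-1.67), with 6 and 5 adjusted over the list alone (camera adjusted p = 0.538). Of 9 tubulins, 7 were lower (7 adjusted over the list alone; median -0.88, camera adjusted p = 0.000524, and adjusted p = 0.392 with an estimated correlation). Interferon-stimulated genes (6 of 28 lower, 6 adjusted over the list alone, median -0.55, camera adjusted p = 0.0142, and adjusted p = 0.866 with an estimated correlation) were lower as a set. So were dsRNA-sensing genes (7 of 16 lower, 8 adjusted over the list alone, median -0.60, camera adjusted p = 0.0181, and adjusted p = 0.755 with an estimated correlation). Both calls were lost without EV vehicle replicate 2 (0.275 and 0.0898, medians -0.16 and -0.46) or p53ERTAM vehicle replicate 1 (0.118 and 0.0510, medians -0.39 and -0.53). The interferon median rested largely on EV vehicle replicate 2. The edgeR test called 6784 genes, 3217 higher and 3567 lower. Gjc3, the muscle receptor kinase Musk and the RNA-binding protein gene Lin28b had no counts in EV vehicle. At the floor of 3 counts they were at least 104-fold, 30.9-fold and 29.1-fold higher in p53ERTAM vehicle. The syntaphilin gene Snph had a log2 fold change of -6.24 (SE 0.611).

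Under combo, p53 targets were higher in p53ERTAM than in EV tumors: 20 of 30 were higher and 2 lower (20 and 2 adjusted over the list alone; median 0.74, camera adjusted p = 2.29e-05, and adjusted p = 0.127 with an estimated correlation). Ccng1 was higher by 2.04 (SE 0.122, edgeR adjusted p = 7.64e-07) and Cdkn1a by 2.42 (SE 0.333, edgeR adjusted p = 0.000170). Mitosis genes were lower (23 of 24, 23 adjusted over the list alone, median -0.86, camera adjusted p = 6.36e-10, and adjusted p = 0.422 with an estimated correlation). DNA replication genes were lower too (17 of 24, 17 adjusted over the list alone, median -0.69, camera adjusted p = 2.60e-07, and adjusted p = 0.422 with an estimated correlation). Interferon-stimulated genes were higher (18 of 28, 23 adjusted over the list alone, median 1.06, camera adjusted p = 1.17e-05, and adjusted p = 0.531 with an estimated correlation). So were 10 of 11 MHC class I genes (10 adjusted over the list alone; median 1.03, camera adjusted p = 0.000366, and adjusted p = 0.422 with an estimated correlation). All 7 of 7 MHC class II genes were higher (7 adjusted over the list alone; median 2.33, camera adjusted p = 0.000610, and adjusted p = 0.422 with an estimated correlation), and 9 of 12 macrophage markers (10 adjusted over the list alone; median 1.75, camera adjusted p = 3.31e-05, and adjusted p = 0.422 with an estimated correlation). T cell markers were higher too (6 of 11, 9 adjusted over the list alone, median 1.94, camera adjusted p = 0.0157, and adjusted p = 0.545 with an estimated correlation), with the T cell receptor subunit Cd3e at 2.61 (SE 0.653) and Cd8a at 3.02 (SE 0.831). Of 16 pyroptosis and necroptosis genes, 7 were higher (7 adjusted over the list alone; median 1.02, camera adjusted p = 0.00218, and adjusted p = 0.422 with an estimated correlation), including Gsdmd (1.05, SE 0.180) and Ninj1 (1.15, SE 0.166), which ruptures the plasma membrane of dying cells.

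Of 15 senescence secretome genes, 12 were higher and 1 lower in p53ERTAM tumors under combo (12 and 1 adjusted over the list alone; median 1.32, camera adjusted p = 0.00144, and adjusted p = 0.422 with an estimated correlation). Among its members, Cdkn2a and Cdkn2b, cell-cycle inhibitor genes and not secreted factors, were higher by 1.26 and 1.33. The growth factor binding protein gene Igfbp5 had a log2 fold change of -2.56. XBP1 targets (14 of 20 higher, 14 adjusted over the list alone, median 0.56, camera adjusted p = 0.000263, and adjusted p = 0.422 with an estimated correlation) were higher. RIDD substrates were also higher (8 of 10 higher, 8 adjusted over the list alone, median 0.83, camera adjusted p = 0.00148, and adjusted p = 0.422 with an estimated correlation). The named genes far down included Fgfr2 (-5.27, SE 0.217), Col17a1 (-5.79, SE 0.422), Krt5 (-5.35, SE 0.672) and Foxi1 (-6.35, SE 0.554), a transcription factor of ion-transporting epithelial cells. As lists, epithelial markers (2 of 10 higher and 2 lower, 2 and 2 adjusted over the list alone, median -0.12, camera adjusted p = 0.80) and basal and mesenchymal markers (4 of 11 higher and 5 lower, 4 and 5 adjusted over the list alone, median 0.65, mean -0.95, camera downward at adjusted p = 0.762) were not called. Named genes far up included Myocd, the smooth-muscle coactivator (7.21, SE 0.662), and Lin28b. Lin28b was absent from EV combo and, at the floor of 3 counts, at least 21.4-fold higher. The edgeR test called 7918 genes, 3966 higher and 3952 lower. NK and cytotoxic cell markers (3 of 7 higher, 5 adjusted over the list alone, camera adjusted p = 0.0448, and adjusted p = 0.531 with an estimated correlation), dendritic cell markers (2 of 8 higher, 2 adjusted over the list alone, 0.0338, and adjusted p = 0.531 with an estimated correlation) and endothelial markers (6 of 10 higher, 7 adjusted over the list alone, 0.0338, and adjusted p = 0.545 with an estimated correlation) were higher as sets. Without EV combo replicate 1 or 2 the calls of NK and cytotoxic (0.102 and 0.0603), dendritic cell (0.0789 and 0.0603) and endothelial markers (0.102 and 0.0603) were lost. Without EV combo replicate 3 the dendritic cell median went from 1.5 to 2.31. The vector differences under vehicle and under combo, which share no library, overlapped in 1164 higher and 1216 lower genes, where independence gives 710 and 785. Another 857 were higher under vehicle and lower under combo (708 by independence) and 364 the reverse (787 by independence). Across genes the 2 log2 fold changes correlated with Pearson's r = 0.11 and Spearman's rho = 0.10.

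Averaged over both vectors, combo left 1243 genes higher and 1756 lower by edgeR. That lead of lower genes was not kept by DESeq2 (1945 higher and 1881 lower) or without the most abundant genes (1357 and 1344). Zbp1 rose by 1.18 (SE 0.261, edgeR adjusted p = 0.0110), a mean of unlike responses. Its mean went from 6.69 to 26.0 CPM in p53ERTAM tumors and from 11.5 to 15.1 CPM in EV tumors. The telomerase RNA gene Terc fell by 1.64 on the log2 scale (SE 0.217, edgeR adjusted p = 0.00109). Spcs3, a subunit of the signal peptidase, fell by 0.88 (SE 0.105) and the growth factor gene Vegfb by 0.91 (SE 0.121). The count of 2999 was 1965 without EV combo replicate 3, 1616 without p53ERTAM vehicle replicate 1, and 1511, 1816 and 1592 without p53ERTAM combo replicates 1, 2 and 3. Averaged over both treatments, p53ERTAM left 3695 genes higher and 3657 lower than EV. Large differences among the named genes with counts in every group included Myocd (6.25, SE 0.437), Foxi1 (-5.65, SE 0.390) and Snph (-5.62, SE 0.406). Gsdmd was higher by 0.84 (SE 0.127, edgeR adjusted p = 0.000169).

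The series' design reads genes raised by combo in EV tumors in the p53ERTAM tumors. Its list of dsRNA-containing genes with p53 binding was not used here, so the 3386 genes higher with combo in EV tumors were read instead. In p53ERTAM tumors these genes had a median log2 fold change with combo of -0.36, and 25.0% lay above 0. The edgeR test called 299 of them lower and 31 higher (camera adjusted p = 1.03e-15, as the only list of its test, and 0.0995 with an estimated correlation, an alternative chosen after seeing the data). The number called lower was 10, 11 and 715 without p53ERTAM vehicle replicates 1, 2 and 3 and 0, 103 and 1 without p53ERTAM combo replicates 1, 2 and 3, while the median stayed between -0.47 and -0.21. TEC genes made up 24.2% of the selection and 6.38% of the genes tested. The 820 TEC genes had a median of -1.10 in p53ERTAM tumors with 128 lower, and the 143 sense intronic genes -1.12 with 22 lower. The 1943 protein-coding genes had a median of -0.12 with 112 lower and 30 higher. Selected and read among protein-coding genes alone, a choice made after seeing the data, 2524 genes had a median of -0.15 with 172 lower and 37 higher (camera adjusted p = 6.95e-07). The selection held 2 of the 30 p53 targets, Polk and Pvt1, the interferon-stimulated genes Herc6 and Mx2, and the dsRNA-sensing genes Adar and Oas1b.

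The mean log2(TPM + 1) of the 3386 genes was 2.49 ± 0.152 (SD, n = 3) in EV vehicle, 3.80 ± 0.0425 in EV combo, 3.12 ± 0.162 in p53ERTAM vehicle and 2.91 ± 0.0980 in p53ERTAM combo. Combo and vehicle in p53ERTAM tumors differed by -0.21 (exact two-sided permutation p = 0.2, adjusted p = 0.2 over 4 comparisons), and 3 tumors against 3 cannot go below 0.1. The values of the EV groups were used to choose the genes and are not an independent comparison.

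**Figure D4:**
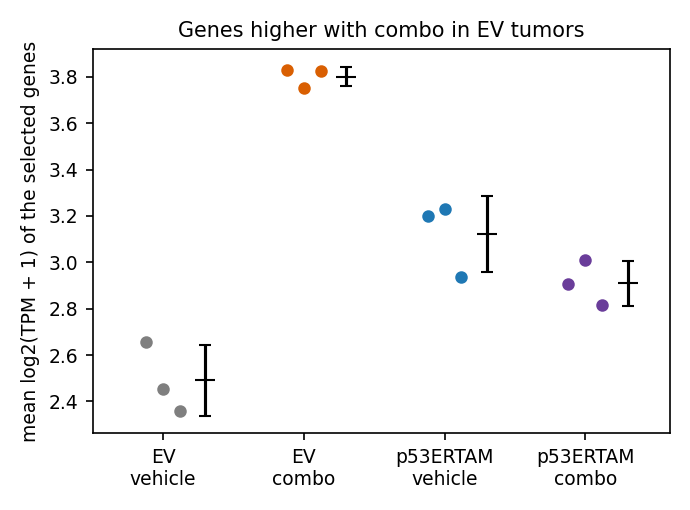
Mean log2(TPM + 1) of the 3386 genes higher with combo in EV tumors, by group; each point is 1 tumor, and the bar and whiskers are the mean and SD of 3 tumors. The genes were chosen on the EV groups; p53ERTAM vehicle lay at 3.12 and p53ERTAM combo at 2.91.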

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

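The tests of EV library make-up, of macrophages, of the tumor share and of epithelial markers below were chosen after the results they measure were seen; those of genomic DNA, unspliced RNA, GC content and length, and the splits of the libraries were chosen after the patterns were seen but before their own results.

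The effect of combo differed between p53ERTAM and EV tumors, by the test of the interaction, for 6473 genes. The median difference, p53ERTAM minus EV on the log2 scale, was 1.52 for interferon-stimulated genes, 0.91 for dsRNA sensing, 1.48 for MHC class I, 2.35 for MHC class II, 1.47 for macrophage markers and 2.70 for T cell markers. It was 0.63 for pyroptosis and necroptosis, 0.59 for p53 targets, 0.65 for XBP1 targets, 0.66 for PERK and ATF4 targets, 0.73 for ATF6 targets and 0.92 for epithelial markers. It was -0.77 for fibroblast markers, -0.80 for basal and mesenchymal markers and -4.41 for erythroid markers. Xbp1 differed by 1.38 and Zbp1 by 1.57. With an estimated correlation the lowest adjusted p of these lists was 0.490. Losses of camera calls when single libraries were left out, beside those given in the report, were pyroptosis and necroptosis (EV vehicle 2, adjusted p = 0.0815, median 0.36; p53ERTAM vehicle 1, 0.0572; with GC and length offsets, 0.0579), T cell markers (EV vehicle 2, 0.0606, median 1.45), basal and mesenchymal markers (EV combo 1, 0.0799, median -0.36; p53ERTAM vehicle 3, 0.138, median -0.55; p53ERTAM combo 2, 0.0773) and erythroid markers (6 libraries, 0.0530 to 0.0848).

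Unannotated and intronic transcripts were higher in the EV combo libraries than in EV vehicle: the 1327 TEC and sense intronic genes tested had a median log2 fold change of 1.85. The tables argue against genomic DNA, since receptor families silent in tumors gained only 0.00183 times as much, in length-scaled CPM, as the median TEC gene. GC content and gene length do not account for the whole, since the median was 1.44 with offsets for both. More unspliced RNA of expressed genes remains a candidate explanation: genes inside protein-coding genes rose by 1.07 more than those outside (95% bootstrap interval 0.79 to 1.37), while their hosts had a median of -0.047. The bootstrap resampled genes, not tumors, so its interval leaves out the spread between tumors. The 192 genes outside rose too, with a median of 0.91. Whether combo or the handling of these 3 tumors raised the TEC and sense intronic genes was not tested.

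Interferon-stimulated genes rose with combo in p53ERTAM tumors and not in EV tumors: their mean score changed by 1.69 and 0.16. The missing rise in EV tumors depended on single libraries. Without EV vehicle replicate 2 the list became a call there (median 0.42, camera adjusted p = 0.0186), and without EV vehicle replicate 3 its median was -0.29. An altered make-up of the EV combo libraries that hides a rise there cannot be told apart from a missing response, since either leaves the score about unchanged, and it changed by 0.16 (95% interval -0.58 to 0.89) against an interaction of 1.53. More macrophages in the p53ERTAM combo tumors cannot be told apart from a response of the tumor cells, since the macrophage score rose by 1.16 (95% interval 0.51 to 1.81) and bulk RNA does not separate the cells. A p53-dependent interferon response to combo may therefore be one explanation among these, and the cell type that carries it stays open.

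Cell-division genes were lower in p53ERTAM than in EV tumors under vehicle, with a median of -1.09 over the 48 members of the mitosis and DNA replication lists. A lower share of tumor cells, with the other cell types in fixed proportion, would raise the markers of those types alike. Instead, fibroblast and endothelial scores rose by 1.44 more than macrophage, T cell and neutrophil scores (95% interval 0.72 to 2.16). This cannot exclude a lower tumor share beside altered proportions of the other cells. Epithelial markers fell as well, by 0.75 (95% interval -1.04 to -0.46), and the mitosis score did not separate from theirs (difference -0.23, 95% interval -0.53 to 0.069), while the DNA replication score fell further (difference -0.35, 95% interval -0.64 to -0.056). Fewer epithelial cells beside more stroma thus stay open for both lists. The further fall of the DNA replication genes would count against an equal fall only if epithelial markers kept their level per cell, which was not tested. GC content and length left the median at -1.06. The p53ERTAM vector of the design stays open as an explanation and was not tested, and the labels do not say which mice received tamoxifen. Growth of fibroblasts and vessels was not excluded as a part of it.

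Splits of the libraries into other groups gave these counts. For comparisons of 3 libraries against 3 the 10 splits are too few for a share under 0.05: 1 of the 10 splits, the real one, called as many genes for combo in EV tumors (7169, highest other 1), combo in p53ERTAM tumors (1129, highest other 3), the vectors under vehicle (6784, highest other 0) and the vectors under combo (7918, highest other 0). For p53ERTAM against EV over both treatments, 1 of 100 splits called as many genes (7352, highest other 3547), so chance is an unlikely source of that count. For the interaction, 1 of 100 splits called as many genes (6473, highest other 2665). These splits exchanged vectors within each treatment, which also removes the vector difference itself. They therefore cannot decide whether chance gave the interaction count. For combo over both vectors, 6 of 100 splits, the real one among them, called at least its 2999 genes (highest other 5478). These splits exchanged treatments within each vector, so a split can keep or mirror the real grouping of 1 vector and with it that vector's response. Whether chance gave the count of 2999 cannot be decided from them.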

How the results depend on the processing

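Chosen after seeing the data were GC and length offsets, halved counts, EV combo left out, protein-coding genes only, and camera with an estimated correlation for the combo-induced genes. Counts stayed within 1.5 times under DESeq2 size factors, no filter, the replicate block (6789, 970, 6341, 7639, 6001, 2408 and 7049 genes), abundant genes left out, GC and length offsets and halved counts. The genes behind the counts moved more with GC and length offsets. Of the 7169 genes called for combo in EV tumors, 5572 stayed called and 70 changed sign. Of the 6473 called for the interaction, 4754 stayed called and 45 changed sign. Replicate numbers did not pair the tumors: 2 of 18 same-numbered pairs correlated above 0.1. Of 52, 53, 50, 58 and 50 named genes called for combo in EV, combo in p53ERTAM, vectors under vehicle, vectors under combo and the interaction, 23, 6, 42, 49 and 35 kept direction and call under every setting, and 0 reversed. The settings include the test against a fold of 1.5, a stricter question than a change of processing. That test by itself ended 24, 46, 5, 7 and 7 of the calls. The camera call of the combo-induced genes was lost with an estimated correlation (median -0.36, p = 0.0995) and held under the other alternatives tried for them, which were fewer than for the counts. The direction held, and the median ranged from -0.57 (genes over 2-fold by mean TPM) to -0.15 (protein-coding genes only). The exact test of their score cannot go below 0.1 with 3 tumors against 3, so its side of 0.05 could not change. The cause was not tested for the changes below unless the setting itself, such as a higher fold or fewer genes or libraries, gives it.

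Against a fold of 1.5 the counts were 1870 for combo in EV tumors, 19 for combo in p53ERTAM tumors, 2078 for vectors under vehicle, 2897 under combo, 2593 for the interaction, 10 for combo over both vectors and 1847 for vectors over both treatments. The direction with more genes also changed for the vectors under vehicle (1219 higher and 859 lower against that fold), the vectors under combo (3713 and 4183 with DESeq2 size factors; 1296 and 1601 against the fold), the vectors over both treatments (3632 and 3736 with the size factors) and combo over both vectors (9 and 1 against the fold). For combo over both vectors it changed by DESeq2 as well (1945 and 1881). It changed for combo in p53ERTAM tumors by DESeq2 (1113 and 1189), by voom with quality weights (1861 and 1887) and without vehicle replicate 3 (984 and 1146). Combo in p53ERTAM tumors gave 2302 genes by DESeq2, 3748 by voom with quality weights, 1890 with only those 2 groups, 627 with EV combo left out of the fit and 77 to 2130 with 1 library left out. The interaction gave 4086 among protein-coding genes, and combo over both vectors 1511 to 3830 with 1 library left out. The mean Trp53 difference of 0.28 was not called against a fold of 1.5, was 0.20 with GC and length offsets, and 0.23 to 0.37 with 1 library left out.

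Values without a call that changed sign follow, with the range over refits without 1 library. For combo in EV tumors they were Trp53 (voom -0.012; -0.057 to 0.21), Esr1 (GC and length -0.050; -0.056 to 0.48), Cdkn1a (voom -0.065; -0.47 to 0.38), Mdm2 (-0.078 to 0.13), Ern1 (GC and length -0.14; -0.043 to 0.11), Gsdmd (-0.014 to 0.28), and the lists dsRNA sensing (-0.083 to 0.23), interferon-stimulated genes (-0.29 to 0.42), RIDD substrates (-0.26 to 0.089) and pyroptosis and necroptosis (by fry, at a median of 0.088; -0.026 to 0.27). In p53ERTAM tumors they were Ern1 (protein-coding -0.0014) and Dnajb9 (-0.041 to 0.45), and under vehicle Dnajb9 (replicate block -0.013; GC and length -0.31; -0.20 to 0.29). For the interaction they were Esr1 (protein-coding -0.068; -0.18 to 0.36), Gsdmd (GC and length -0.017), Mdm2 (DESeq2 -0.024; size factors -0.024; GC and length -0.088; protein-coding -0.16; -0.062 to 0.17) and Ern1 (DESeq2 -0.019; size factors -0.020; protein-coding -0.15; -0.057 to 0.10). Depth limits rare transcripts: at 3 counts over a group the floor was 0.0409 to 0.0636 CPM.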

Other observations

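Igf2, a fetal growth factor gene singled out after its values were seen, was among the most abundant transcripts and fell with combo in both kinds of tumor. It took 2.50 ± 0.705% of the counts (SD, n = 3) in EV vehicle, 1.28 ± 0.116% in EV combo, 0.983 ± 0.127% in p53ERTAM vehicle and 0.418 ± 0.0391% in p53ERTAM combo. Its log2 fold change with combo was -0.97 (SE 0.195, edgeR adjusted p = 0.00203) in EV and -1.27 (SE 0.196, edgeR adjusted p = 0.00626) in p53ERTAM tumors. Between the vectors it was -1.43 (SE 0.197, edgeR adjusted p = 0.000200) under vehicle and -1.73 (SE 0.199, edgeR adjusted p = 3.13e-05) under combo.

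Several other cell-type lists had at most 1 member called in p53ERTAM tumors given combo. Neutrophil markers had 0 of 9 members called (0 adjusted over the list alone, median -0.025, camera adjusted p = 0.994), dendritic cell markers 0 of 8 (0 adjusted over the list alone, median 0.82, camera adjusted p = 0.0531), and B and plasma cell markers 0 of 3 (0 adjusted over the list alone, median 2.28, camera adjusted p = 0.230). Adipocyte markers had 1 of 5 higher (1 adjusted over the list alone, median 1.65, camera adjusted p = 0.110), milk protein genes 1 of 4 higher (1 adjusted over the list alone, median 0.32, camera adjusted p = 0.453), and keratinocyte markers 0 of 3 called (1 lower adjusted over the list alone, median -0.044, camera adjusted p = 0.419). The only skeletal muscle marker measured was not called there (log2 fold change 0.98, camera adjusted p = 0.385). In EV tumors given combo 0 of 9 neutrophil and 0 of 5 adipocyte markers were called (0 and 0 adjusted over the list alone; camera adjusted p = 0.278 and 0.968), and the same muscle marker was higher (4.77, camera adjusted p = 0.312).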
